A study of Mus musculus with 6 samples.

How the data were processed

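RNA-seq was run on 6 libraries from NP-specific IgG1 light zone germinal centre B cells of C57BL/6 mouse spleen, 3 of high and 3 of low affinity. Per the labels' protocols, total RNA was extracted with Trizol from cells sorted from 10 mice and pooled, libraries were made with the NEBNext Ultra kit, and sequencing was on an Illumina instrument. The antigen gate that defined affinity, the time after immunisation and the read length are not given in the sources used here. TopHat2 2.0.8, Cufflinks 2.1.1 and the mouse genome build mm9 are named in the submitters' processing notes, with no role or order; the gene annotation and the options are not given in the sources used here.

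Each deposited file is a Cufflinks gene tracking table per the file headers, with 1 row per gene locus and the authors' FPKM value, its status and the bounds of its interval. FPKM divides fragments by transcript length and by the library's mapped fragments, so a value is relative to all other transcripts in its library, and no further scaling between libraries is stated. The bounds were not used, because between 1026 and 1307 rows per file had an FPKM above its own upper bound. In each file 285 rows had the status for too little data. One gene, Actr3, had a failed estimate and was listed at 0 in low affinity libraries 2 and 3, against 580 to 603 FPKM in the other 4, and was left out.

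Depth is not stated. Relative depth was estimated from genes under 1 FPKM in all libraries, as the most frequent ratio of high affinity library 1 to each other library. This takes the most frequent ratio as that of single fragments, which was not checked. With high affinity library 1 set to 1, the estimate was 1.30 and 0.81 for high affinity libraries 2 and 3. It was 1.23, 1.09 and 1.18 for low affinity libraries 1, 2 and 3. Total FPKM was 688644, 683320 and 739619 in high affinity libraries 1, 2 and 3, and 554018, 578834 and 578912 in low affinity libraries 1, 2 and 3. No counting interval can be given without counts, so the spread between the 3 libraries of a group is the only error used.

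Rows sharing a gene symbol were summed (250 symbols lay on more than 1 locus), giving 23234 symbols. Values were taken to log2(FPKM + 1), and the 10038 genes with a mean of at least 1 FPKM over the 6 libraries were tested for high minus low affinity with limma 3.58.1 in R 4.3.3 (moderated two-sided test with an intensity trend, no covariates). P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. No count model was used, since the values are not counts. Gene lists were tested with limma's camera (two-sided, inter-gene correlation of 0.01), adjusted over the 24 program lists and, separately, the 5 cell type marker lists with at least 5 tested members, out of 25 and 9 lists. Camera asks whether a list moved more than the other genes. With the correlation estimated from these 6 libraries, no list passed in either family (5 program lists and 1 marker list at an unadjusted p under 0.05), while fry, which asks whether the genes of a list move on balance one way, gave 23 program lists and 1 marker list.

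The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Named genes were the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, leaving out unnamed clones, predicted genes, microRNAs and small nucleolar RNAs (1040 tested, 423 past the threshold), 17 genes of germinal centre biology fixed in advance, and up to 4 members of smallest p of each list described. Of the 17, Prdm1 lay below the filter and Ighg1 had no row used here. Some genes that the rule names are not reported here. The alternatives were another pseudocount (0.1), no filter on low values or a minimum mean of 5 FPKM, 3 scalings (median of ratios, quantile normalization, equal totals without immunoglobulin genes), the highest row per symbol, robust variances, no intensity trend, library weights, the replicate number as a block, an estimated correlation, fry, and leaving out each library. Igj was the only tested gene that equal totals without immunoglobulin genes left out. Removing a trend on transcript length or on GC content was added after seeing the data. Lengths and GC content came from the longest GENCODE M21 transcript of each symbol, matched by name, with older symbols matched through RefSeq; 9912 of the 10038 tested genes (98.7%) had a value. Those annotations are on another build than mm9, so none of their coordinates are used. Loci are the files' own, on mm9, with starts counted from 1.

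The code was tested on simulated data with the real genes' means and spreads. In the simulated comparison of high and low affinity over 10038 genes, 38 of 100 genes changed 1.5-fold, 37 of 50 changed 2-fold and 50 of 50 changed 4-fold were recovered, with 4 false calls. Only these genes changed there, and genes were drawn independently with no shift between libraries. In the data 5061 genes passed, so these rates check the code and do not carry over to the real comparison. Figures were drawn with matplotlib 3.10.9.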

Results

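The data were RNA-seq expression profiles of germinal centre B cells sorted from the spleen of C57BL/6 mice. The cells carried an IgG1 B cell receptor specific for NP, a small hapten used as a model antigen, and came from the light zone, the part of the germinal centre in which B cells take up antigen and receive signals from follicular helper T cells. They were sorted by flow cytometry into a high affinity and a low affinity population. There were 3 libraries of each population, and cells of 10 mice were pooled for sorting per the labels. The labels do not say that the libraries came from separate pools, so the p-values below measure only the spread between these samples, which may be technical. Each deposited file gave 1 FPKM value (fragments scaled by transcript length and by sequencing depth) per gene locus. The files give no read counts, so the absolute depth is unknown. Relative depth was estimated from the most frequent ratio of low values between libraries, taken as that of single fragments. It lay between 0.81 and 1.30 times that of high affinity library 1. The study's single contrast asked which transcripts differ between light zone B cells of high and of low affinity.

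Among 10038 genes tested, 5061 passed the threshold (limma's moderated test, adjusted p under 0.05), with 3068 higher and 1993 lower in the high affinity libraries. A log2 fold change of at least 1 was reached by 586 of the higher genes, and one of at most -1 by 379 of the lower genes. High affinity cells had more of the transcripts for ribosome biogenesis, mitochondrial respiration, DNA replication and mitosis. Low affinity cells had more of the transcripts for B cell receptor signalling, antigen presentation on MHC class II, T cell help and memory B cells. Of 24 program lists tested with camera at a preset correlation between genes, 20 passed, 10 up and 10 down. Several lists share members, such as Cd83, Cd40 and Rel in both the light zone and the NF-kB and CD40 lists, so the calls are not independent. With the correlation estimated from these libraries no list passed in camera (lowest adjusted p = 0.181, with 5 at an unadjusted p under 0.05). Among program lists the estimates ran from 0.031 (T cell help genes) to 0.706 (ribosomal protein genes), against the preset 0.01. MHC class II genes had 0.645. The camera p-values of single lists below thus hold at the preset correlation only. Another test of limma, fry, gave 23. Equal totals below means equal totals without immunoglobulin genes, and it moves the median log2 fold change of all genes from 0.08 to -0.18. This scaling left out only Igj (10037 genes tested against 10038), so it does not test the share of immunoglobulin transcripts in the totals. Libraries of the same group correlated with r of 0.938 to 0.957 across genes, and libraries of different groups with r of 0.891 to 0.915; genes are not independent replicates. The groups did not overlap for 60.3% of tested genes, against 10% by chance.

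**Figure D1:**
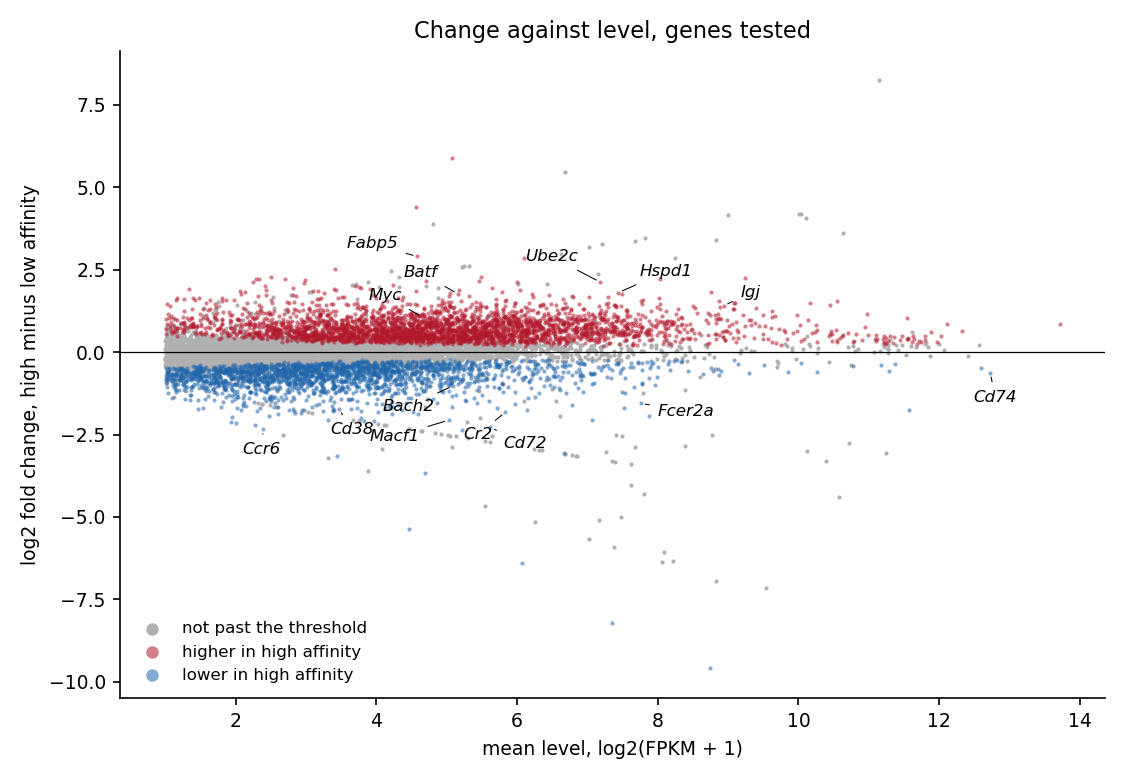
The log2 fold change (high minus low affinity, on log2(FPKM + 1)) of each of the 10038 tested genes against its mean level; red and blue points passed the threshold and grey points did not. Red points (3068) outnumber blue points (1993); with libraries scaled to equal totals without immunoglobulin genes the counts were 1716 and 3354.

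The transcription factor Myc, a driver of cell growth, was 33.1 ± 4.92 FPKM in high affinity and 15.3 ± 1.99 FPKM in low affinity cells (SD, n = 3 each; log2 fold change 1.07 ± 0.14 (SE), adjusted p = 0.000558). All 39 tested Myc target and ribosome biogenesis genes rose, with a median log2 fold change of 1.14 (camera adjusted p = 3.02e-16). Among them were the chaperonin Hspd1 (269 ± 13.5 against 76.6 ± 7.43 FPKM), the growth-associated protein gene Pa2g4 (245 ± 10.9 against 90.9 ± 2.26 FPKM) and Ran and Ranbp1 of nuclear transport (Ranbp1 696 ± 35.9 against 235 ± 15.2 FPKM). Oxidative phosphorylation genes rose in 38 of 38 cases, with a median of 0.67 (camera adjusted p = 2.35e-11). Fewer rose under other processing: 23 rose and 1 fell under quantile normalization (median 0.316), 28 rose and 1 fell with the length trend removed (0.394), and 29 rose with equal totals (0.375). Cytochrome c, encoded by Cycs, was 92.8 ± 8.40 against 38.1 ± 0.706 FPKM, and the ATP synthase subunit gene Atp5b 608 ± 37.1 against 304 ± 14.3 FPKM. Of 17 glycolysis genes, 12 rose, none fell and 5 did not pass (median 0.73; camera adjusted p = 0.000104). With equal totals 11 rose and 2 fell (median 0.427), and under quantile normalization 13 rose and 1 fell (0.473). Examples were lactate dehydrogenase Ldha, at 586 ± 8.70 against 256 ± 10.8 FPKM, and Tpi1, at 209 ± 7.39 against 90.4 ± 3.40 FPKM. Of 27 mTORC1 and amino acid uptake genes, 20 rose, 3 fell and 4 did not pass (median 0.58; camera adjusted p = 0.000659). With equal totals only 9 rose (median 0.29), and under quantile normalization 15 (0.334). The serine synthesis enzymes Phgdh (136 ± 11.7 against 50 ± 2.60 FPKM) and Psat1 (133 ± 8.40 against 54.8 ± 4.83 FPKM) were among those that rose. Adjusted over the list alone, the counts of these 4 lists were the same.

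Ribosomal protein genes rose in 61 of 81 cases, 1 fell and 19 did not pass; 67 rose and 1 fell adjusted over the list alone. Their median log2 fold change was 0.36 (camera adjusted p = 2.28e-09). Rpl14 was 1555 ± 77.3 against 880 ± 28.9 FPKM, and Rps2 2783 ± 345 against 1238 ± 51.9 FPKM. These genes are short, with a median transcript length of 1094 nt, and short genes as a class had higher fold changes (median 0.33 in the shortest of 4 length classes, -0.144 in the longest). The call ended when the length trend was removed (median 0.03, adjusted p = 0.46) and under quantile normalization (median 0.08, adjusted p = 0.0595; range over all alternatives at the preset correlation 4.59e-13 to 0.46). With equal totals the list passed, but its median was 0.066, with 27 genes higher and 6 lower.

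Genes of cell division were higher in high affinity cells. All 32 tested mitosis genes rose, with a median log2 fold change of 1.35 (camera adjusted p = 1.31e-14). The ubiquitin-conjugating enzyme Ube2c was 235 ± 20.2 against 53.0 ± 2.89 FPKM, the anaphase activator Cdc20 103 ± 9.57 against 23 ± 2.12 FPKM, and cyclin A2, encoded by Ccna2, 150 ± 4.34 against 48.8 ± 1.24 FPKM. Of 34 DNA replication genes, 30 rose, none fell and 4 did not pass (median 0.67; camera adjusted p = 9.22e-09). With equal totals 21 rose (median 0.378), and under quantile normalization 23 (0.382). Both subunits of ribonucleotide reductase rose, with Rrm1 at 141 ± 7.59 against 67.1 ± 1.32 FPKM and Rrm2 at 196 ± 16.7 against 88.9 ± 3.47 FPKM. Of 28 somatic hypermutation and DNA repair genes, 15 rose, 3 fell and 10 did not pass (median 0.48; camera adjusted p = 0.00805). With equal totals 10 rose and 5 fell (median 0.191), and with the GC trend removed 15 rose and 5 fell. Polh, the polymerase that writes mutations at A:T pairs, was 42.9 ± 2.91 against 22.8 ± 2.19 FPKM. With a minimum mean of 5 FPKM the repair list no longer passed (adjusted p = 0.0559; range over all alternatives at the preset correlation 0.000218 to 0.0559). These 3 lists had the same counts when adjusted over the list alone.

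Although all cells were sorted as light zone cells, 14 of 16 dark zone genes rose and 2 fell (median 1.23; camera adjusted p = 2.86e-05), with the same counts adjusted over the list alone; 1 fell without high affinity library 1 or without low affinity library 1, 2 or 3. The dark zone is where germinal centre B cells divide and mutate, and 9 of the 16 genes are also in the mitosis list. Outside that list, Cxcr4, the chemokine receptor that holds cells in the dark zone, was 93.2 ± 12.7 against 48.6 ± 5.79 FPKM (log2 fold change 0.92 ± 0.13 (SE), adjusted p = 0.000847). The transcription factor gene Foxo1, which is needed for the dark zone state, was lower, at 12.6 ± 1.95 against 18.2 ± 0.954 FPKM (log2 fold change -0.51 ± 0.12 (SE), adjusted p = 0.00966; adjusted p = 0.0782 with the length trend removed, the highest of a range from 0.00226).

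Of 23 light zone genes, 13 fell, 2 rose and 8 did not pass (median log2 fold change -0.36; camera adjusted p = 9.01e-05). With equal totals 17 fell (median -0.648), and under quantile normalization 15 (-0.617). The costimulatory ligand gene Cd86 was 59.8 ± 6.16 FPKM in high affinity and 135 ± 11.3 FPKM in low affinity cells, and the light zone surface marker Cd83 136 ± 16.1 against 232 ± 11.9 FPKM. Cd40, the receptor for T cell help, was 44.7 ± 4.34 against 57.1 ± 4.39 FPKM, a smaller fall whose call was lost without high affinity library 2 (adjusted p = 0.0625) and without low affinity library 2 or 3 (0.0699 and 0.0742; range over all alternatives 0.000793 to 0.0742). The 2 members that rose were Myc and Batf; Batf, a transcription factor of activated lymphocytes, was 54.5 ± 13.3 against 15.1 ± 1.45 FPKM. Of 23 T cell help receptor and ligand genes, 15 fell, none rose and 8 did not pass (median -0.50; camera adjusted p = 8.83e-06), and 18 fell with equal totals (median -0.793). Icosl, the ligand of ICOS on follicular helper T cells, was 9.31 ± 1.53 against 37.0 ± 1.38 FPKM, and the interleukin 4 receptor gene Il4ra 18.3 ± 2.15 against 39.8 ± 2.72 FPKM. Of 28 NF-kB and CD40 response genes, 13 fell, 2 rose and 13 did not pass (median -0.29; camera adjusted p = 0.00411). Fewer NF-kB and CD40 response genes fell without high affinity library 2 (8) or without low affinity library 2 or 3 (8 and 7), and more with equal totals (17, median -0.575) or under quantile normalization (16, -0.491). The NF-kB subunit gene Rel was 22.2 ± 4.89 against 42.4 ± 2.30 FPKM, and Il4i1 32.3 ± 9.86 against 107 ± 4.37 FPKM. Counts adjusted over the list alone were the same for these 3 lists.

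Transcripts of B cell receptor signalling were lower in high affinity cells in 23 of 30 cases, with none higher and 7 not passing (median log2 fold change -0.54; camera adjusted p = 2.28e-09). Under quantile normalization and with equal totals 27 of the B cell receptor signalling genes fell (medians -0.835 and -0.834). The list holds inhibitory receptors, of which Cd22 was 108 ± 7.13 against 249 ± 13.8 FPKM and Cd72 16.0 ± 3.99 against 80.6 ± 7.83 FPKM. Among 22 immediate early genes, which are induced within minutes of receptor stimulation, 14 fell, 1 rose and 7 did not pass (median -0.60; camera adjusted p = 4.56e-05). Egr3 was 1.23 ± 0.347 against 6.62 ± 1.22 FPKM, Fos 18.3 ± 3.52 against 46.9 ± 1.71 FPKM and Nr4a1 1.31 ± 0.242 against 4.55 ± 0.475 FPKM. The activation marker Cd69 was 16.2 ± 2.05 against 26.8 ± 5.08 FPKM. Of 14 MHC class II presentation genes, 13 fell, none rose and 1 did not pass (median -0.52; camera adjusted p = 8.69e-06), and 14 fell under quantile normalization and with equal totals (medians -0.851 and -0.821). Ciita, the master activator of MHC class II genes, was 49.9 ± 2.89 against 92.6 ± 4.47 FPKM, and H2-Ob 110 ± 17.7 against 260 ± 12.7 FPKM. Of 15 MHC class I presentation genes, 6 fell, 2 rose and 7 did not pass (median -0.157, and -0.461 under quantile normalization, -0.084 without high affinity library 1 and -0.252 without high affinity library 3; camera adjusted p = 0.0909; 0.0378 without high affinity library 3, range over all alternatives at the preset correlation 0.000351 to 0.137), with Nlrc5, their transcriptional activator, at 2.85 ± 0.133 against 9.39 ± 0.866 FPKM. Counts adjusted over the list alone did not differ for these 4 lists.

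Bach2, a transcriptional repressor that restrains plasma cell differentiation and favours memory B cells, was 21.5 ± 1.60 FPKM in high affinity and 44.7 ± 1.81 FPKM in low affinity cells (log2 fold change -1.02 ± 0.09 (SE), adjusted p = 0.000119; lower in 3 of 3 libraries). It lies on mm9 chromosome 4 from 32504410 to 32673083. Of 21 memory B cell genes, 11 fell, 2 rose and 8 did not pass, also adjusted over the list alone (median -0.71; camera adjusted p = 0.00181). The median of memory B cell genes was -0.368 with no filter (24 genes) and -1.097 with a minimum mean of 5 FPKM (12 genes). Ccr6, a chemokine receptor of memory B cells (chromosome 17, 8428908 to 8449994), was 0.772 ± 0.583 against 7.74 ± 0.646 FPKM. Cd38, which germinal centre B cells of the mouse lose and memory B cells carry (chromosome 5, 44260066 to 44303613), was 4.18 ± 1.24 against 16.0 ± 2.46 FPKM. The complement receptor gene Cr2 was 24.2 ± 3.99 against 87.7 ± 5.95 FPKM, and Foxp1 4.95 ± 0.470 against 12.4 ± 0.781 FPKM. Cr2, Cd38, Il4ra and the IgE receptor gene Fcer2a (111 ± 24.3 against 322 ± 6.89 FPKM) are also among the 12 markers of naive follicular and marginal zone B cells, a list in which 5 fell and none rose (camera adjusted p = 0.178; 0.0451 without high affinity library 3, range over all alternatives at the preset correlation 0.0308 to 0.545).

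Of 23 germinal centre identity genes, 12 fell, 6 rose and 5 did not pass, and 13 fell and 6 rose adjusted over the list alone (median log2 fold change -0.24; camera adjusted p = 0.0184). Under quantile normalization and with equal totals, 16 germinal centre identity genes fell and 2 rose (medians -0.639 and -0.536), and with the length trend removed 14 fell and 4 rose (-0.551). Bcl6, the defining repressor of the germinal centre, was 65.7 ± 5.23 against 99.2 ± 5.49 FPKM. The histone methyltransferase gene Ezh2 was higher, at 100 ± 7.23 against 58.6 ± 5.26 FPKM, as was Gcet2, at 72.0 ± 3.48 against 37.6 ± 0.840 FPKM. S1pr2, the receptor that confines cells to the germinal centre, was 98.3 ± 5.51 against 105 ± 3.14 FPKM (log2 fold change -0.10 ± 0.07 (SE), adjusted p = 0.278), and passed as lower under each of the 3 other scalings (adjusted p = 0.0429, 0.00193 and 0.0075) and with the GC trend removed (0.0407; highest over all alternatives 0.622, with the length trend removed). Of 23 migration and adhesion genes, 13 fell, 2 rose and 8 did not pass, also adjusted over the list alone (median -0.27; camera adjusted p = 0.00147). Without low affinity library 3 only 8 migration and adhesion genes fell, with equal totals 16 (median -0.567) and under quantile normalization 14 (-0.599). With the length trend removed 12 fell (-0.433). Cxcr5, which guides B cells into the follicle, was 69.1 ± 2.14 against 124 ± 7.63 FPKM, and S1pr3 10.7 ± 0.709 against 22.1 ± 0.969 FPKM.

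Transcripts of the plasma cell programme were higher in the high affinity libraries for part of the list. Whether they came from germinal centre cells or from plasma cells in the sort was not tested. The same holds for the unfolded protein response genes below. Of 20 plasma cell genes, 9 rose, 4 fell (2 without low affinity library 2 or 3) and 7 did not pass, also adjusted over the list alone (median log2 fold change 0.42; camera adjusted p = 0.0853; 0.031 without high affinity library 1, range over all alternatives at the preset correlation 0.00265 to 0.451). With equal totals, which leaves out Igj, 6 plasma cell genes rose and 5 fell (median 0.133), and the median was 0.17 under quantile normalization and 0.235 with the length trend removed. With no filter 12 rose, 2 fell and the list passed (adjusted p = 0.00265). The J chain gene Igj was 714 ± 79.0 against 267 ± 8.54 FPKM, and the secretory regulator Xbp1 90.1 ± 5.62 against 47.3 ± 4.45 FPKM. Irf4, a regulator of plasma cell differentiation, was 7.53 ± 0.749 against 5.50 ± 0.656 FPKM (log2 fold change 0.39 ± 0.13 (SE), adjusted p = 0.033), a call lost in 8 of 19 alternatives, among them median of ratios and equal totals scaling, no filter (0.0603), the replicate block (0.0656), the GC trend removed (0.112), without high affinity library 2 (0.0919) and without low affinity library 2 or 3 (0.105 and 0.119; range over all alternatives 0.0208 to 0.467). Prdm1, which encodes the plasma cell regulator Blimp-1, lay below the filter, at 1.20 ± 0.231 against 0.0774 ± 0.0510 FPKM; without the filter its log2 fold change was 1.02 (adjusted p = 0.00092). Of the 7 tested plasma cell markers, chosen to detect other cells in the sort, 6 rose and 1 did not pass (median 0.92, and 0.594 over 6 genes with equal totals, where 4 rose; camera adjusted p = 0.0156, not past the threshold with an estimated correlation); all 7 are also in the plasma cell list, so the lists are not independent. Of 23 unfolded protein response genes, 16 rose, 3 fell and 4 did not pass, also adjusted over the list alone (median 0.43; camera adjusted p = 0.00411). With equal totals 11 rose and 4 fell (median 0.144). The chaperone gene Hsp90b1 was 257 ± 28.0 against 96.6 ± 8.22 FPKM and Sdf2l1 91.3 ± 6.10 against 32.1 ± 3.81 FPKM, while the ubiquitin ligase gene Syvn1 was lower, at 43.2 ± 1.85 against 78.6 ± 4.91 FPKM. Under quantile normalization 10 rose, 4 fell and this list no longer passed (median 0.191, adjusted p = 0.0622; range over all alternatives at the preset correlation 0.000143 to 0.0622).

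Neither list of apoptosis genes passed in camera with the deposited scaling; in fry the pro-apoptotic list passed (adjusted p = 0.0243) and the anti-apoptotic list did not (0.141). Of 12 anti-apoptotic genes, 3 fell and 1 rose (camera adjusted p = 0.231; range over all alternatives at the preset correlation 0.0488 to 0.506). With the length trend removed the list passed, with 7 lower and a median of -0.378 against -0.075. Mcl1 was 86.1 ± 3.45 against 117 ± 2.29 FPKM. Of 17 pro-apoptotic genes, 6 fell and 4 rose (camera adjusted p = 0.231), but 2 rose without high affinity library 1 or 2 or without low affinity library 1 or 3, and none with equal totals, where 8 fell. Among those that fell was Bmf, which triggers cell death, at 3.36 ± 0.489 against 12.3 ± 0.865 FPKM. The rise of Trp53, at 87.5 ± 5.58 against 64.6 ± 1.17 FPKM, did not pass under quantile normalization or with equal totals. Of 15 interferon response genes, 6 fell, 1 rose and 8 did not pass (median log2 fold change -0.41; camera adjusted p = 0.00523). With equal totals 10 interferon response genes fell (median -0.645). Stat2 was 6.40 ± 0.998 against 12.8 ± 1.29 FPKM, while Bst2 was higher, at 21.3 ± 1.60 against 10.9 ± 0.223 FPKM. Counts adjusted over the list alone were the same for these 3 lists.

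**Figure D2:**
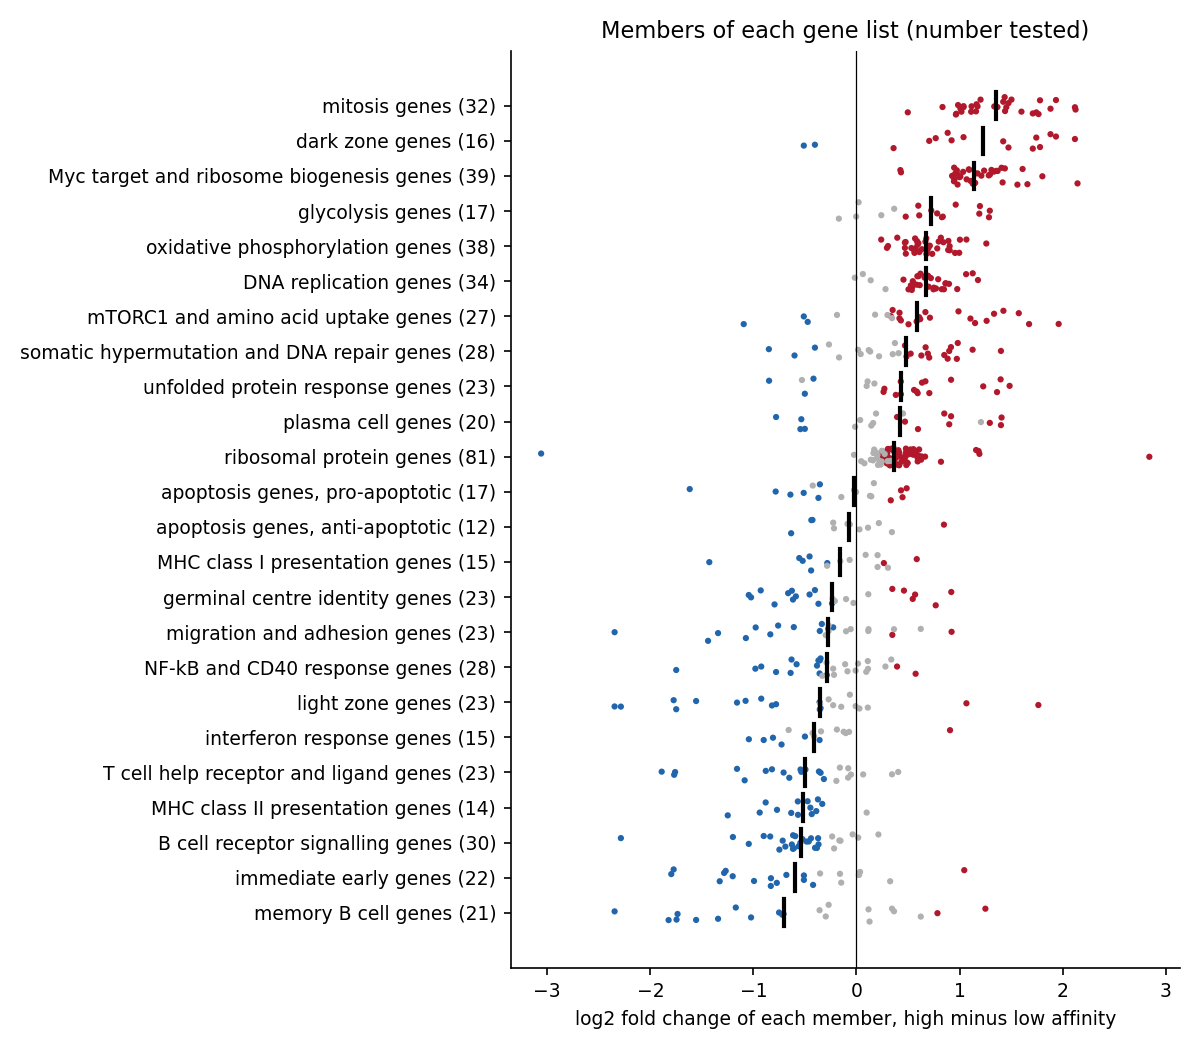
The log2 fold change (high minus low affinity) of each tested member of the 24 program lists, with the number tested in brackets and a black bar at the list's median; red members rose, blue members fell and grey members did not pass. With the deposited scaling and the fixed filter, the medians run from -0.71 for memory B cell genes to 1.35 for mitosis genes.

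The largest rises by the fixed rule included Fabp5, a fatty acid binding protein gene (41.1 ± 6.61 against 4.78 ± 1.72 FPKM, log2 fold change 2.90), Gsto1, a glutathione transferase gene (17 ± 1.12 against 2.21 ± 0.785 FPKM, 2.52), Ppa1, a pyrophosphatase gene (73.1 ± 3.58 against 14.4 ± 1.48 FPKM, 2.27), and the protease inhibitor gene Slpi (432 ± 93.7 against 91.5 ± 4.51 FPKM, 2.21). Fam195a, BC048355 and Nme4, at log2 fold changes of 2.22, 2.21 and 2.21, were also among the 10. The remaining 3 are uncertain. Snhg9 (4.39), a small RNA host gene next to Rps2, was listed at 0 in 2 of the 3 low affinity libraries, Rpl26 (2.84) has pseudogene copies that can share its reads, and Ifitm6 (2.27) ran with granulocyte transcripts, at 1.93, 7.69 and 16.2 FPKM in high affinity libraries 1, 2 and 3, and did not pass without high affinity library 2 or 3 (adjusted p = 0.0673 and 0.0597) or low affinity library 2 or 3 (0.0699 and 0.086; range over all alternatives 0.00445 to 0.0916). The largest falls included Ccr6 (-2.35) and Cd72 (-2.29), Rasgef1b (0.790 ± 0.643 against 6.93 ± 0.393 FPKM, -2.21), the translation inhibitor gene Pdcd4 (4.88 ± 1.52 against 24.3 ± 6.86 FPKM, -2.10) and Macf1, which links actin to microtubules (11.6 ± 0.277 against 51.7 ± 2.17 FPKM, -2.06). Ppl (-2.11), Serpinb1a (-2.10) and Ceacam16 (-2.07) completed the list with Pisd-ps1 (-3.16) and Rps27 (-3.06). The last pair are a pseudogene and a gene with pseudogene copies; Rps27 ranged from 17.5 to 380 FPKM within the low affinity libraries, and did not pass without high affinity library 1, 2 or 3 (adjusted p = 0.0734, 0.0919 and 0.068) or low affinity library 1 or 3 (0.108 and 0.0974; range over all alternatives 0.000619 to 0.122), so it is uncertain.

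**Figure D3:**
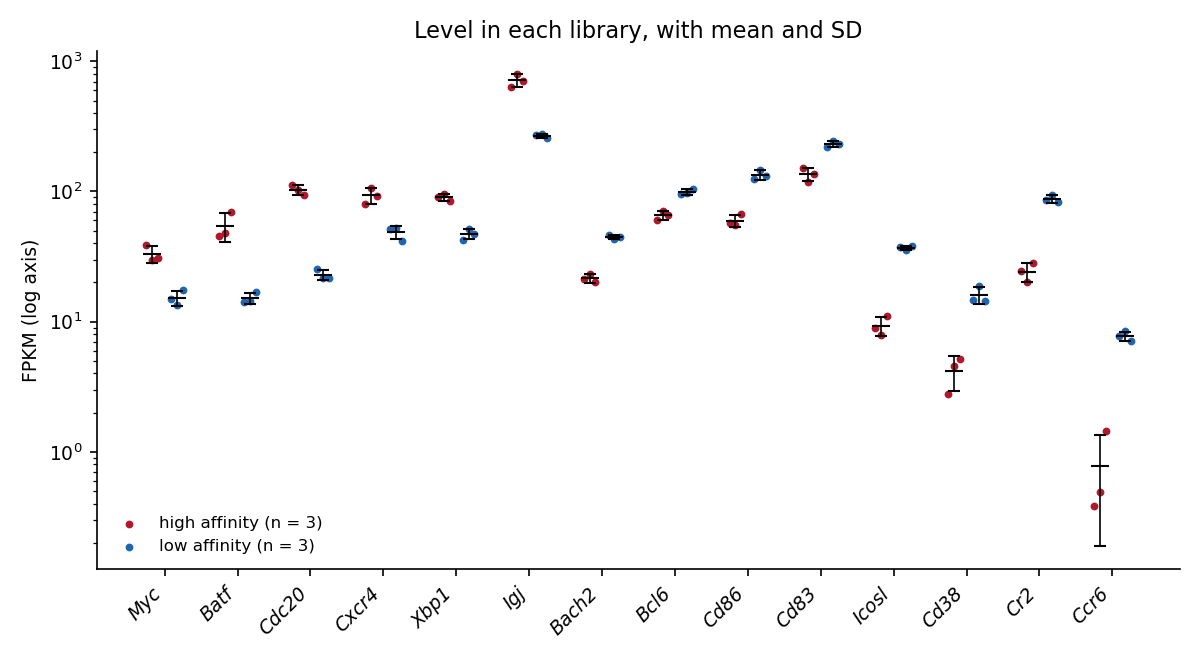
FPKM of 14 genes in each library, on a log axis, with a point per library and black bars for the mean and SD of the 3 libraries of a group. For each of these genes the 3 high affinity points (red) lie on 1 side of the 3 low affinity points (blue), as for Ccr6, at 0.383 to 1.44 against 7.11 to 8.40 FPKM.

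Markers of granulocytes and of red cells varied between libraries of the same group. The summed FPKM of monocyte, macrophage and granulocyte markers was 12.7, 884.9 and 1200.1 in high affinity libraries 1, 2 and 3, and 272.0, 54.9 and 106.5 in low affinity libraries 1, 2 and 3; none of the 9 tested members passed (median log2 fold change 0.955, camera direction down, adjusted p = 0.926). In high affinity libraries 2 and 3 granulocyte genes made up most of the sum. The most abundant, S100a8, named after its values were seen, was listed at 0 in high affinity library 1 and was 375 and 452 FPKM in high affinity libraries 2 and 3, and Ngp was listed at 0, 59.6 and 72.1 FPKM in the same libraries. Neither passed with all libraries (adjusted p = 0.828 and 0.354), and both passed as higher without high affinity library 1 (0.0174 and 0.0207; highest over all alternatives 0.979 and 0.706), as did 6 of the 9 members of the list. Erythroid markers summed to 45.8, 218.2 and 276.3 FPKM in high affinity and 131.3, 120.2 and 136.5 FPKM in low affinity libraries, and none of 6 passed (median 0.04, camera direction down, adjusted p = 0.926). Of 8 T cell markers, Cd2 fell, at 20.0 ± 7.45 against 54.4 ± 3.71 FPKM, and Tox rose, at 19.7 ± 1.54 against 13.8 ± 0.521 FPKM, a call lost with equal totals (adjusted p = 0.163; range over all alternatives 0.00219 to 0.163). The T cell list did not pass (camera adjusted p = 0.926). Its members Cd3e, Cd3g and Cd4 were at most 1.56, 6.07 and 0.55 FPKM in any library, below Cd2 and Tox. Whether Cd2 and Tox came from T cells was not tested. NK cell, dendritic cell and platelet markers had too few tested members for a test (2, 2 and 1), and stromal and follicular dendritic cell markers and immunoglobulin constant region genes, Ighg1 among them, had none. Summed NK cell markers were at most 10.3 FPKM, platelet markers at most 7.8 FPKM and stromal markers at most 1.5 FPKM in any library, while dendritic cell markers summed to 23.5 to 35.8 FPKM, with Bst2, also an interferon response gene, the largest part in the high affinity libraries.

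Total FPKM was 703861 ± 31082 in the high affinity and 570588 ± 14350 in the low affinity libraries (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows), so the balance of higher and lower calls depended on scaling. Of the calls, 60.6% were higher as deposited, 51.6% after median of ratios scaling, and 33.8% (1716 higher, 3354 lower) with equal totals without immunoglobulin genes.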

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

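Removing the length or GC trend was chosen after seeing the data; the other alternatives were planned. The count of genes past the threshold (5061) stayed between 4242 and 5326 over the alternatives that kept all 6 libraries, and between 4003 (without low affinity library 3) and 4999 (without high affinity library 3) with 1 library left out. Of the 5061 genes, 4637 also passed after median of ratios scaling, all in the same direction, and 4188 with the length trend removed, 4181 of them in the same direction. Equal totals without immunoglobulin genes gave 1716 higher and 3354 lower genes, because the scaling lowers high affinity values relative to low affinity values. The count of program lists (20) was 19 to 23 elsewhere, and 0 in camera with an estimated correlation, where 5 lists had an unadjusted p under 0.05; fry gave 23. For cell type marker lists (1) that count was also 0, with 1 at an unadjusted p under 0.05, and with a minimum of 5 FPKM it was 2, since the naive B cell list then passed. With 1 library left out it was 1 to 2, with 2 without high affinity library 3. No shared effect of the replicate number was seen, since the deviations of same-numbered libraries correlated at -0.058, -0.095 and 0.032. Whether same-numbered libraries came from the same mice is not known. The fit with a replicate block called 4783 genes.

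For lists of other cells that passed nowhere, the direction of the list test turned between settings, and the cause was not tested. At these turns the medians of T cell markers and of monocyte, macrophage and granulocyte markers stayed positive, as with the main settings. The medians at the turns were, for T cell markers, 0.41 with a pseudocount of 0.1 and 0.11 with the length trend removed. They were 0.212 to 0.256 without high affinity library 2 or 3 or low affinity library 3, and 0.212 to 0.544 over all single libraries left out. For monocyte, macrophage and granulocyte markers they were 0.076 with no filter, 0.885, 0.718 and 0.701 under median of ratios, quantile and equal totals scaling, 0.955 in fry, 0.83 with the GC trend removed, 1.14 without low affinity library 1 and 2.70 without high affinity library 1; without high affinity library 3 the median was -0.44 and the direction did not turn. For erythroid markers they were 0.20 with no filter, -0.18 with equal totals and 1.36 without high affinity library 1; without high affinity library 3 the median was -0.309 and the direction did not turn. Of genes, S1pr2, which did not pass, was 0.038 with the length trend removed. S100a8 was -0.416 with a pseudocount of 0.1, -0.07 with library weights, and -0.878 without high affinity library 3 to 3.53 without high affinity library 1. Plac8 was -0.073 without high affinity library 3 and 1.53 without high affinity library 1. Depth limits genes of low level, since the depth is known only relative to 1 library.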

Other observations

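Further members of the fixed lists, named after their values were seen, stood far apart between the groups. The interleukin 10 receptor gene Il10ra was 2.14 ± 0.836 FPKM in high affinity and 9.46 ± 0.352 FPKM in low affinity cells (SD, n = 3 each; log2 fold change -1.77, limma adjusted p = 0.000284), and Tnfrsf14, a receptor that restrains B cell growth, 2.76 ± 1.70 against 10.7 ± 0.795 FPKM (-1.76, adjusted p = 0.00426). Hhex, a homeobox transcription factor gene of memory B cells, was 2.76 ± 1.63 against 10.9 ± 0.717 FPKM (-1.75, adjusted p = 0.00149), and the integrin gene Itgb7 3.70 ± 1.15 against 10.7 ± 1.01 FPKM (-1.34, adjusted p = 0.00102). In the opposite direction, Cd24a, a surface glycoprotein gene, was 877 ± 27.4 against 511 ± 69.0 FPKM (0.79, adjusted p = 0.000639) and Zbtb32 2.36 ± 0.0284 against 0.429 ± 0.255 FPKM (1.25, adjusted p = 0.00107). All 3 libraries of each group lay apart for these 6 genes. The plasma cell surface genes Sdc1 and Tnfrsf17 lay below the filter. Sdc1 was 1.42 ± 0.720 against 0.0263 ± 0.0229 FPKM, and Tnfrsf17 was 1.71, 0.820 and 1.85 FPKM in high affinity libraries 1, 2 and 3 and listed at 0 in the low affinity libraries.

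The tests of scaling, of length on rising and falling lists apart, of the GC trend in fold changes, of length on ribosomal protein genes, of dark zone cells, of dividing cells and of resting B cells were chosen after the results were seen. Program lists moved in both directions, 10 up and 10 down. Gene length was related to the change across genes: in the shortest of 4 length classes (median 1371 nt) 43.7% rose and 10.3% fell, and in the longest (median 5995 nt) 15.5% rose and 30.6% fell. With the length trend removed the 20 lists kept on average 1.10 times their median change, and 1.04 times with the GC trend removed. These averages mix falls that grew with rises that shrank, partly because the median of all genes moved from 0.075 to -0.004 and -0.007. Relative to that median, the rising lists kept on average 0.919 of their change without the length trend and the falling lists 1.148, which argues against length as the whole cause. The fold change was almost unrelated to GC content (Spearman -0.031 over 9912 genes), and its GC trend had an SD of 0.049, or 0.082 of the mean absolute list median relative to all genes, which argues against GC content. Single lists differed: oxidative phosphorylation genes kept 0.586 of their median without the length trend, taken as it is, and the median of ribosomal protein genes went from 0.36 (SD over 81 genes 0.52) to 0.03 (0.535). Its call ended because the median shrank at a like spread, so a bias by gene length may account for that rise.

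Total FPKM was higher in the high affinity libraries, and a test of a list against other genes hardly sees a scaling that shifts all genes alike. The medians themselves did change. Under equal totals without immunoglobulin genes the rising lists kept on average 0.54 of their median, from 0.183 for ribosomal protein genes, 0.333 for unfolded protein response genes, 0.399 for hypermutation and repair genes and 0.498 for mTORC1 genes to 0.784 for mitosis genes. Relative to the median of all genes they kept 0.939 there, 0.98 with median of ratios and 0.661 under quantile normalization, though a shift of all genes alike can hardly change the first 2 of these. Taken gene by gene, at least 95.8% of 71 mitosis and Myc target genes still passed as higher under each of the 3 scalings. All of them had risen as deposited, with list medians of 1.353 and 1.139, and these lists were picked after that was seen. The scalings moved the median of all genes less, from 0.075 to -0.184 at most, so most calls were bound to stay. The values show only that the rise of these genes was larger than those shifts. For the rising and falling lists as sets, how much comes from scaling cannot be told apart from a change in the cells, because the RNA content per cell was not measured in the data used here. FPKM is already divided by mapped fragments, so its total also depends on the lengths of the transcripts that hold them. Total FPKM and the length trend need not be separate causes. The falling lists kept on average at least 1.237 times their median, but each of the 3 scalings lowers the high affinity values relative to the low affinity values, which enlarges falls on average whatever their cause, so this decides nothing. A difference between the affinity groups stays open as a hypothesis for both.

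Dark zone genes were higher in the high affinity libraries of a light zone sort. If dark zone cells had entered the high affinity gate, dark zone genes outside the mitosis list would rise too: 5 of these 7 rose, with a median of 0.71 over all 7, but 2 fell, Foxo1 among them. If the high affinity light zone held more dividing cells, DNA replication genes would rise, and their median was 0.67, which dark zone cells would bring as well. In the same libraries 13 of 23 light zone genes fell and 2 rose, a fall that dark zone cells in the gate would also bring. Whether more dividing cells would lower light zone genes was not tested. The 2 explanations cannot be told apart, because each raises genes of division and the zone gate was not analysed here.

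Cr2, Fcer2a, Cd38 and Il4ra, which mark resting B cells, were lower in the high affinity libraries. They are among the 5 genes that fell of 12 tested markers of naive follicular and marginal zone B cells. The median log2 fold change of all 12 was -0.071. A candidate explanation is a larger share of naive or memory B cells in the low affinity sort. The other 8 tested markers of that list had a median of 0.36, between -0.60 (Cd55) and 0.91 (Plac8); 1 fell and none rose past the threshold, and the fall of Cd55 was lost without low affinity library 1 or 2 (adjusted p = 0.0522 and 0.0509; range over all alternatives 0.00382 to 0.0522). Taking out genes that had fallen raises the median of the rest whatever the cause, so that median decides nothing. The other 8 also went both ways, and Plac8 was raised in high affinity library 3 only (64.5 FPKM against 6.07 and 9.33 FPKM in high affinity libraries 1 and 2). The test thus leaves the explanation open. A lower level of these genes within high affinity germinal centre cells cannot be told apart from it, and the IgG1 gate would remove unswitched naive cells.

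The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 5061 genes and the highest of the others 5, with 1 split as large as the real one, itself. Each other split mixes the affinity groups, so a difference between them adds to the spread and leaves few genes to pass. Their gene counts thus do not show what chance alone would give. The real split gave 20 program lists and the highest of the others 18, with 1 split as large. It gave 1 cell type marker list and the highest of the others 4, with 7 splits as large. Splits that mix the affinity groups thus also gave many list calls at the preset correlation.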
